A study of Mus musculus with 8 samples.

How the data were processed

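RNA was measured on 8 Affymetrix whole-transcript arrays, each of mammary epithelial cells from FVB mice in a first pregnancy or lactation, 4 arrays at day 14 of pregnancy and 4 at day 4 of lactation. Per the labels' protocols, adipocytes were removed by enzymatic digestion of the tissue, total RNA was extracted with Trizol, cleaned on a column with DNase digestion, and converted to biotin-labelled sense-strand DNA for hybridisation. The values the authors deposited are log2 values per probe set and array, made with GC-RMA, a method that corrects the background by probe sequence, normalizes between arrays and summarises the probes of each probe set. GCRMA and Partek are named per the submitters' processing notes, while their versions and options, the annotation release and the genome build are not given in the sources used here, so no coordinates are printed. Because the deposited values were already normalized, no further normalization was applied, and differences in the total amount of RNA per cell are not measured.

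The deposited table held 35556 probe sets, of which 26836 carried a gene symbol and 8720 did not. Control probe sets could not be separated from unannotated ones among the latter, and these 8720 were left out of the gene tests. Only the leading gene of each probe set is named in the table, so a probe set shared by several genes carries 1 name. Symbols were updated with the RefSeq gene table of assembly GRCm38.p6, used for names only. By accession 22040 probe sets were matched, 3611 by current symbol and 143 by a unique synonym, and 1042 kept the name given in the table. The update changed 1099 symbols and left 25050 genes. For the 975 genes with more than 1 probe set, the probe set with the highest mean over all 8 arrays was used. In 3 of these genes, probe sets passed the threshold in opposite directions. A second deposited table held the same values, with a largest difference of 0. No column of values was left unused.

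Groups were taken from the sample titles. Lactation was compared with pregnancy in limma 3.58.1 (R 4.3.3), with a linear model per gene, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over the 25050 genes. A gene was called at an adjusted p under 0.05, and a log2 fold change of 1 or more in size was counted as at least 2-fold. No filter on dim genes was applied. Replicate numbers were not used as a block. The number of arrays limits the precision: the median half-width of the 95% confidence interval of a log2 fold change was 0.21. GC-RMA values ran from 2.04 to 13.03, and differences of genes near either end can be compressed. Probe sets of near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Acot1, Orm1 and the Gsdmc family) can share signal, so their values are uncertain as to the member.

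Before the data were examined, 30 gene lists of 505 genes were fixed, 18 by function and 12 by cell type, from textbook knowledge. Of these entries 4 had no probe set under their symbol (Acsl3, Mbtps2, Hbb-b1 and Hbb-b2). Some lists share genes, so their results are not independent. Prolactin and progesterone signalling shares 8 with hormone-sensing luminal cells, and the LXR list 5 with cholesterol transport. Milk proteins share 4 with the milk fat globule list, and tight junctions 2 with luminal markers. Each list was tested with camera in limma, which asks whether its members move differently from other genes, with a preset correlation between genes of 0.01 and adjustment over the 30 lists. Alternatives were camera with a correlation estimated per list and fry, which asks whether members move on balance in a single direction, without comparing them with other genes. The genes named in the text were set by a rule fixed at the same time: the 15 largest rises and 15 largest falls with all 4 arrays of a stage above the other stage, leaving out predicted genes, immunoglobulin and T cell receptor segments, small RNA genes and olfactory or vomeronasal receptors; up to 4 members of each list with the largest called changes, with both directions where they existed; and 19 genes of sterol and lactation biology named in advance. It gave 127 genes, of which 122 passed the threshold. Some of the 127 are withheld and not reported here. A few further genes are identified in the text as chosen afterwards.

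The procedure was tested on simulated data for lactation against pregnancy with the real genes' means and spreads. Of 25050 genes, 67 were shifted by 0.5 log2 units, 67 by 1 and 66 by 2, and 68.66%, 98.51% and 100% of these were recovered. False calls made up 7 of 185 calls. None of the 30 lists was called in simulated data without change, and camera recovered a shifted list of 20 genes with an adjusted p of 3.72e-47. The simulated noise was independent between genes, so false calls of lists with correlated members were not tested. The estimated correlation reached 0.868 in the real data, for T cell markers. Alternatives covered the variance model, a filter on the dimmest 40% of genes, quantile normalization, centring of arrays on all genes, on reference genes or on the brighter 60% of genes, the probe set rule, array weights, the replicate number as a block and leaving out each array. All 35 splits of the 8 arrays into 4 and 4 were refitted. Intervals of list medians came from 10000 bootstrap draws over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.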

Results

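The series asks how mammary epithelium handles cholesterol as it begins to secrete milk, with the liver X receptors (LXR), nuclear receptors activated by oxysterols, named in its title. Gene expression was compared between secretory differentiation, at day 14 of pregnancy, and secretory activation, at day 4 of lactation, in mammary epithelial cells depleted of adipocytes, on 4 arrays per stage. No LXR agonist or receptor mutant was among the samples analysed here. The labels do not tie arrays to separate mothers, so p-values measure the spread between these samples, which may be technical. Arrays correlated at 0.9865 to 0.9925 within lactation, 0.9898 to 0.9951 within pregnancy and 0.9644 to 0.9777 between the stages, across genes, which are not independent replicates. The leading principal component held 62.2% of the variance and separated the stages. No arrays were duplicates, since the smallest SD of the difference between any 2 arrays was 0.229 log2 units.

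At lactation day 4 the most strongly induced gene was the casein Csn1s2b, at 12.31 ± 0.07 against 6.35 ± 0.56 on the log2 scale (SD, n = 4 per stage), a 62.1-fold rise with a log2 fold change of 5.96 (SE 0.225, limma adjusted p = 4.42e-07). It was followed by Atp2b2, the calcium pump of the apical membrane (4.78), Gsdmc, a gasdermin (4.65), the chemokine Ccl28 (4.59), Ddah1, which breaks down methylarginines (4.54), and Plpp4, a lipid phosphatase (3.96). Egf, Orm1, the lipid droplet protein Cidea, Pcp4, the carbonic anhydrase Car4, the sterol sensor Insig1, Steap1, Tc2n and the milk peroxidase Lpo rose by 3.31 to 3.81. Cyp1b1, a cytochrome P450, fell by 4.00, from 8.33 ± 0.35 to 4.34 ± 0.18, followed by the Wnt agonist Rspo1 (-3.70), the metallothionein Mt2 (-3.65), the zinc importer Slc39a4 (-3.59) and the receptor Kit (-3.53). Acot1, Anpep, Plscr2, Dusp4, Muc4, BC006965, Lgr6, Atp6v1b1 and Phlda1 fell by 3.03 to 3.47.

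Of 25050 genes, 6463 (25.8%) passed the threshold in limma, 2438 of them higher and 4025 lower at lactation day 4. A change of at least 2-fold was found for 397 higher and 428 lower genes. All 4 arrays of a stage lay above those of the other in 29.6% of genes, where chance gives 2.86%. Without pregnancy day 14 replicate 3, the number of higher genes was 1537. The split between directions moved with the scaling. Lower genes were 62.3% of those called, but 53.2% after quantile normalization, 47.1% with arrays centred on their median, 52.0% with arrays centred on the reference genes and 18.0% with arrays centred on the brighter 60% of genes, a choice made after seeing the data that shifted the median of all genes from 0.01 to 0.19.

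**Figure D1:**
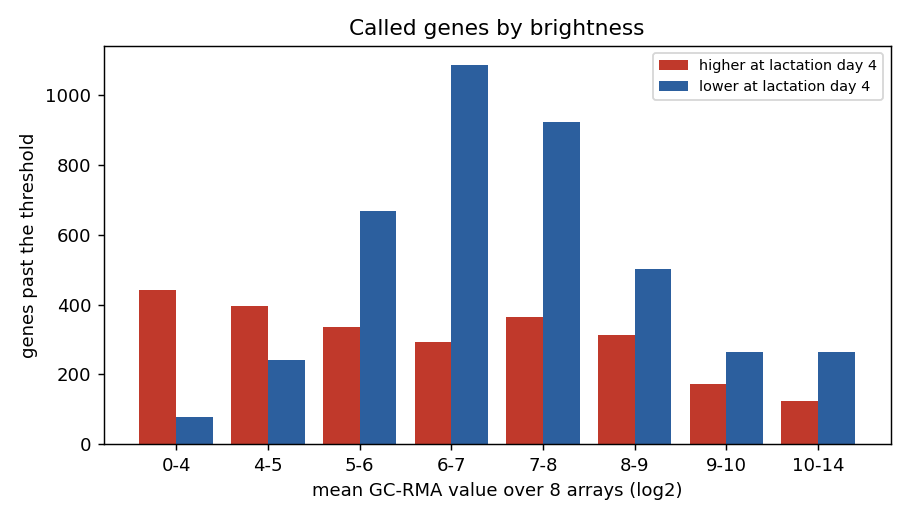
Number of genes past the threshold (vertical axis) that were higher (red) or lower (blue) at lactation day 4, in 8 ranges of mean GC-RMA value over the 8 arrays (horizontal axis, log2). Higher genes outnumbered lower ones among the dimmest genes, 441 against 77 below a value of 4, and lower genes outnumbered higher ones between 6 and 7, 1087 against 292.

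Milk protein genes rose. Among 18 measured, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 0.72. Csn1s2b, Lpo (3.31) and the mucin Muc1 (2.23) rose most and Muc4, a membrane mucin, fell by 3.20. The abundant Csn2, beta-casein, rose from 12.36 ± 0.05 to 12.72 ± 0.07, close to the highest value on any array, 13.03, so its change of 0.36 may be understated. Wap rose by 0.85 and Lalba, the regulatory subunit of lactose synthase, by 1.12. The list was called by camera (limma, adjusted p = 1.84e-11), with adjusted p = 0.0934 with an estimated correlation.

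Genes of the milk fat globule and lipid droplet rose in 10 of 14 cases and 1 fell (11 and 1 adjusted over the list alone). Cidea (3.51), Muc1 and Rab18, a small GTPase of lipid droplets (2.05), rose, and Plin2, a lipid droplet coat protein, fell by 0.29 (adjusted p = 0.021 in limma, a call that ended under 6 of 18 alternatives). Camera in limma gave an adjusted p of 3.84e-07, and adjusted p = 0.0934 with an estimated correlation. Calcium, ion and nutrient transporters rose in 17 of 28 cases and fell in 3 (17 and 3 adjusted over the list alone), led by Atp2b2, the metal transporter Slc39a8 (2.92) and the phosphate carrier Slc34a2 (2.80), while the amino acid carrier Slc6a14 fell by 1.17. The list's adjusted p in limma's camera was 7.30e-07, and adjusted p = 0.0934 with an estimated correlation. In the lactose and sugar supply list, 7 of 13 genes rose and 2 fell (7 and 4 adjusted over the list alone), with Hk2 (1.13) and Lalba among the rises and Gpi1, a glycolytic isomerase, down (-0.61). That list missed the threshold in limma's camera (adjusted p = 0.062) but passed it under several alternatives (0.0129 without pregnancy day 14 replicate 4, for example).

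In the endoplasmic reticulum list, 9 of 24 genes rose and 2 fell (10 and 2 adjusted over the list alone). Trib3 (1.35), Edem1 (0.72) and Dnajc3 (0.65) rose and Ern1, a sensor of unfolded protein, fell by 0.64. Limma's camera gave an adjusted p of 0.0641 for the list, and several alternatives passed the threshold, with 0.0269 without lactation day 4 replicate 1 and 0.00702 without pregnancy day 14 replicate 4.

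Fatty acid synthesis genes rose at lactation day 4, 20 of 25, and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 1.11. Acacb, an acetyl-CoA carboxylase, rose by 2.57 (SE 0.184), Slc25a1, the mitochondrial citrate carrier, by 2.48, the desaturase Scd2 by 2.43 and Fasn by 0.99, and Mcat, of mitochondrial fatty acid synthesis, fell by 0.35. All 20 measured cholesterol synthesis genes rose (20 adjusted over the list alone), with a median of 1.35. The largest of these rises were those of Cyp51 (2.21, SE 0.161), Msmo1 (2.18), Tm7sf2 (2.03) and Acat2 (2.00). Camera in limma called fatty acid synthesis at an adjusted p of 1.02e-18 and cholesterol synthesis at 4.29e-20, and both kept the call with an estimated correlation (adjusted p = 0.013 for each). They were the only 2 of the 14 called lists to do so. A call lost under that alternative does not by itself show correlated members. Triglyceride synthesis, with an estimated correlation of -0.00738 against the preset 0.01, went from a camera adjusted p of 0.062 to 0.217.

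**Figure D2:**
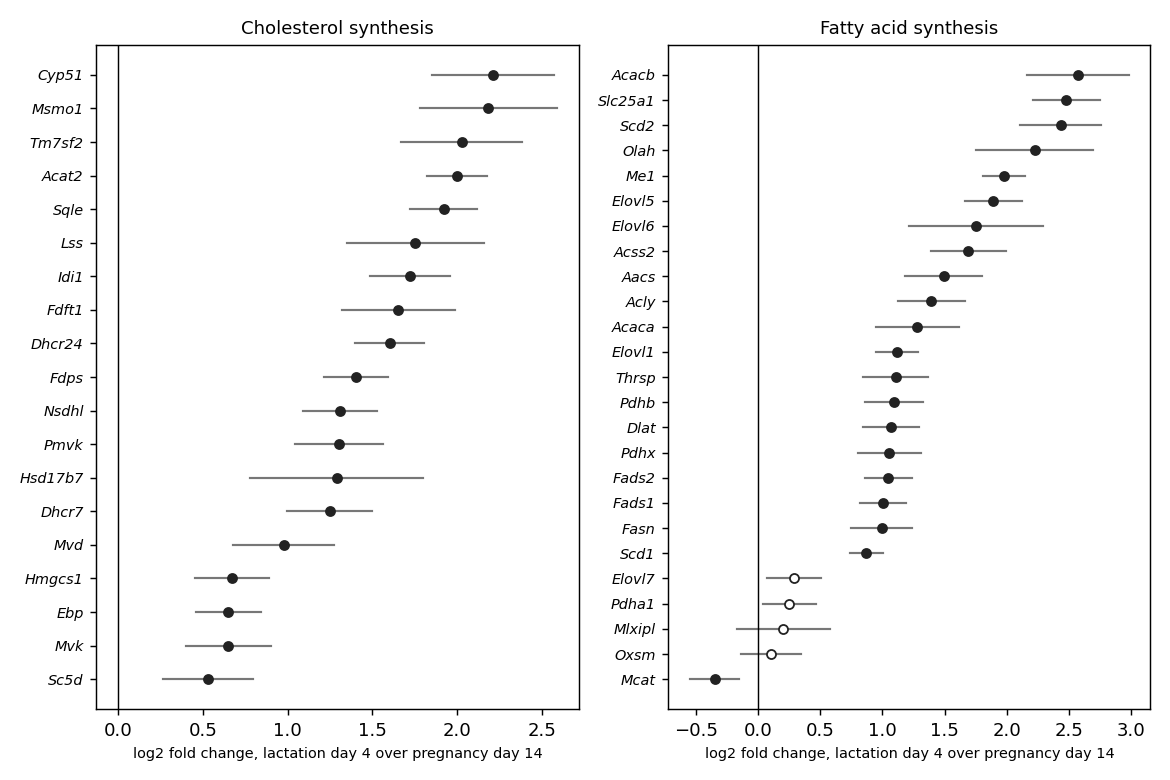
Log2 fold change of lactation day 4 over pregnancy day 14 (horizontal axis) for 19 of the 20 measured genes of cholesterol synthesis (left) and all 25 of fatty acid synthesis (right), 4 arrays per stage. Points are limma estimates, lines 95% confidence intervals, and filled points passed an adjusted p of 0.05, as did all 19 cholesterol genes shown and 21 of 25 fatty acid genes, of which Mcat fell.

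Fatty acid oxidation genes fell, 17 of 26 against 2 that rose (18 and 2 adjusted over the list alone), with a median of -0.72. Acadl, an acyl-CoA dehydrogenase, fell by 2.22, Cpt1a, which admits fatty acids to mitochondria, by 1.74 and the carnitine carrier Slc25a20 by 1.33, while the receptor Ppara rose by 0.56. Limma's camera gave an adjusted p of 6.27e-09, and adjusted p = 0.0652 with an estimated correlation. In fatty acid uptake and activation 7 of 15 genes rose and 3 fell (7 and 3 adjusted over the list alone), with Lpl, lipoprotein lipase (1.31), Cd36 (0.96) and Fabp5 (0.92) up and the fatty acid transporter Slc27a1 down (-1.47). That list's adjusted p in limma's camera was 0.0393, with adjusted p = 0.229 with an estimated correlation, and the call ended under several alternatives, among them arrays centred on their median (0.0903), on the reference genes (0.0544) or on the brighter genes (0.235), and without lactation day 4 replicate 3 (0.0813) or 4 (0.0928). For triglyceride synthesis 5 of 18 genes rose and 1 fell (6 and 1 adjusted over the list alone), with Lpin1 (1.60), Aldoc, a glycolytic aldolase (1.15), and Agpat1 (1.11) up and Agpat3 down (-1.25). Its adjusted p was 0.062 in limma's camera and passed the threshold under several alternatives, with 0.0425 without lactation day 4 replicate 2, 0.0264 after quantile normalization and 0.014 without the dimmest genes.

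Both LXR genes were lower at lactation day 4. Nr1h3, encoding LXR alpha, fell from 5.86 ± 0.23 to 5.21 ± 0.11 (log2 fold change -0.65, SE 0.123, limma adjusted p = 0.00396), and Nr1h2, encoding LXR beta, fell by 0.28 (adjusted p = 0.022 in limma, 0.104 after quantile normalization, a call that ended under 7 of 18 alternatives). The sterol exporter Abca1, a known LXR target, fell by 1.75 (SE 0.252, limma adjusted p = 0.00091) to 6.28 ± 0.62, and Abcg1 by 0.78. Apoc1, an apolipoprotein, fell by 1.18. With the mean of the macrophage markers added to the limma fit, Abca1 kept its call (adjusted p = 0.00853). The calls of Nr1h3 (0.066), Nr1h2 (0.147), Abcg1 (0.103) and Apoc1 (0.0633) ended, at log2 fold changes of -0.555, -0.268, -0.507 and -1.02. The SE of each of these genes rose with that term, and calls over all genes went from 6463 to 2674. Abcg2, an apical transporter of the mammary gland, rose by 1.80 (SE 0.203, limma adjusted p = 0.000236) and Abca7 by 0.33 (adjusted p = 0.0321 in limma, 0.0817 without pregnancy day 14 replicate 4, a call that ended under 6 of 18 alternatives). The sterol exporters Abcg5 and Abcg8, with log2 levels of 4.06 and 4.27 in lactation, had log2 fold changes of 0.01 and 0.22 (limma adjusted p = 0.943 and 0.0588).

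Over the list of LXR and its known targets, 12 of 29 genes fell and 4 rose (12 and 5 adjusted over the list alone), the rises including Lpl and Fasn. The list as a whole was not called by camera in limma (adjusted p = 0.338) or by fry (0.594). The macrophage markers described below were also lower, with a median of -0.63, and macrophages express Abca1 and Abcg1. In cholesterol transport, storage and efflux 10 genes rose and 10 fell of 32 (11 and 10 adjusted over the list alone), with the lipoprotein receptor Lrp8 (1.39) and Abcg2 up and Abca1 down, and limma's camera gave an adjusted p of 0.64.

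Within SREBP regulation and sterol sensing 5 of 17 genes rose and 1 fell (5 and 1 adjusted over the list alone). Insig1, a sterol-regulated retention protein, rose by 3.46 (SE 0.201) and the sterol carrier Stard4 by 1.14, and Erlin2, an endoplasmic reticulum protein, fell by 0.46. Srebf1 and Srebf2, encoding the transcription factors, had log2 fold changes of 0.23 and 0.22 (limma adjusted p = 0.204 and 0.13). Limma's camera gave the list an adjusted p of 0.0194, with adjusted p = 0.322 with an estimated correlation, and 0.0695 without lactation day 4 replicate 4 or 0.0761 with arrays centred on the brighter genes. Of 16 oxysterol and bile acid genes, Acox2 rose by 0.48 and Scp2 fell by 0.38, a call that ended under 10 of 18 alternatives (1 and 0 adjusted over the list alone), Cyp27a1, a sterol hydroxylase, had a log2 fold change of -0.13 (limma adjusted p = 0.425), and the list's adjusted p in camera was 0.528.

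**Figure D3:**
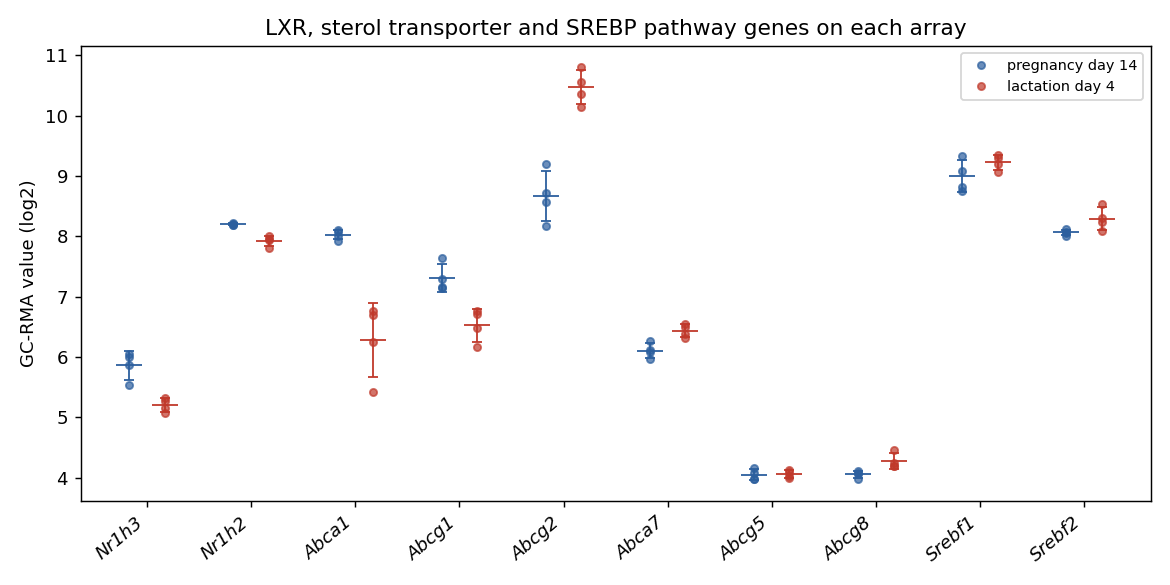
GC-RMA value (vertical axis, log2) of 10 genes of LXR, sterol transport and the SREBP pathway on each of 4 arrays at pregnancy day 14 (blue) and 4 at lactation day 4 (red), with bars for the mean and lines for its SD. Abca1 fell from 8.03 to 6.28 and Abcg2 rose from 8.66 to 10.47, while Abcg5 lay at 4.05 and 4.06.

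Prolactin and progesterone signalling genes fell more often than they rose. In the prolactin and progesterone list 11 of 24 fell and 3 rose (11 and 3 adjusted over the list alone), with Igfbp5, an insulin-like growth factor binding protein (-3.01), Tph1, of serotonin synthesis (-1.23, a call that ended under 11 of 18 alternatives), Gata3, a luminal transcription factor (-0.999), and Stat5a (-0.37) down, and Prlr, the prolactin receptor (0.96), and Esr1, the estrogen receptor (1.19), up. The list's adjusted p was 0.0282 in limma's camera, with adjusted p = 0.229 with an estimated correlation, and 0.341 without the dimmest 40% of genes. Tight junction genes fell in 9 of 18 cases and rose in 1 (12 and 1 adjusted over the list alone). The claudins Cldn1 (-2.61), Cldn4 (-2.24) and Cldn3 (-1.94) fell and Cldn8 rose (0.93), at an adjusted p of 2.73e-04 in limma's camera, with adjusted p = 0.186 with an estimated correlation.

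In the proliferation list Mki67, the Ki-67 antigen, rose by 0.96, while Mcm7, a replication helicase subunit, fell by 0.97 and Bub1b by 0.44 (ended under 7 of 18 alternatives), and 29 of 32 genes missed the threshold (1 rose and 1 fell adjusted over the list alone). Its median of 0.05 and mean of -0.01 differ in sign, and limma's camera gave an adjusted p of 0.932. Lactation day 4 replicate 3 had a list mean of -0.51 against 0.10 to 0.19 on the other lactation arrays, and without it the list was higher in lactation (adjusted p = 0.0381).

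Luminal epithelial markers fell in 11 of 15 cases with none rising (11 adjusted over the list alone), with a median of -0.96. Kit fell by 3.53, Cldn4 by 2.24, Cldn3 by 1.94 and the keratin Krt19 by 1.34, at an adjusted p of 7.56e-09 in limma's camera, with adjusted p = 0.0934 with an estimated correlation. Hormone-sensing luminal markers went both ways, with Esr1, Prlr and Ly6a (0.71) up and Pgr, the progesterone receptor (-0.82), among 3 down of 11 (3 up and 4 down adjusted over the list alone), and their median of -0.23 and mean of 0.05 differ in sign (limma camera adjusted p = 0.956). Among 12 basal and myoepithelial markers Krt17 rose by 1.10 and Krt14 fell by 0.75 (1 and 1 adjusted over the list alone), with a list adjusted p of 0.955.

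Of 14 T cell markers 10 fell (13 adjusted over the list alone), among them Cd3e (-1.50), Cd3g (-1.47), Il7r (-1.45) and Cd4 (-1.36). Fibroblast markers fell in 8 of 15 cases (9 adjusted over the list alone), among them Fn1 (-1.43), Col1a2 (-1.14), Col1a1 (-1.09) and Mfap5 (-1.08), the calls of which ended under 5, 5 and 7 of 18 alternatives, and macrophage markers in 3 of 14 (3 adjusted over the list alone), namely Lyz2 (-1.31), Cd68 (-1.23) and Mrc1 (-0.97, ended under 5 of 18 alternatives). No member of these lists rose past the threshold. Camera in limma gave adjusted p-values of 1.31e-04, 7.49e-04 and 0.0108, all lost with an estimated correlation (adjusted p = 0.59 with an estimated correlation for T cells, 0.602 for fibroblasts and 0.622 for macrophages) and with fry (adjusted p = 0.075, 0.0818 and 0.121). As small a camera p was found in 13, 18 and 17 of the 35 splits of the arrays, and the macrophage call also ended without the dimmest 40% of genes (adjusted p = 0.13).

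Red blood cell genes fell in 5 of 9 cases (5 adjusted over the list alone), including Hba-a2 (-1.06), Alas2 (-1.05), Hba-a1 (-1.03) and Hbb-bs (-0.53, ended under 5 of 18 alternatives), with a list adjusted p of 0.062 in limma's camera that passed the threshold under several alternatives, with 0.0201 without lactation day 4 replicate 1, 0.0224 without pregnancy day 14 replicate 1 and 0.0489 without pregnancy day 14 replicate 4. All 12 B and plasma cell markers had negative log2 fold changes, of which only that of Blnk (-1.05) passed the threshold (1 adjusted over the list alone), with a list adjusted p of 0.0527 that passed the threshold under several alternatives, with 0.0201 and 0.0283 without lactation day 4 replicates 1 and 3 and 9.31e-04 without pregnancy day 14 replicate 4. S100a8 (-0.32, a call that ended under 12 of 17 alternatives) fell among 11 neutrophil markers (0 adjusted over the list alone; list adjusted p = 0.309). No endothelial marker of 14 and no skeletal muscle marker of 11 passed the threshold in limma (0 adjusted over each list alone), with list adjusted p-values of 0.932 and 0.2. Adipocyte markers Lep (1.18) and Adig (0.95) rose, 2 of 15 (2 adjusted over the list alone), with a list adjusted p of 0.428 and list means from -1.11 on pregnancy day 14 replicate 4 to 0.68 on lactation day 4 replicate 1.

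**Figure D4:**
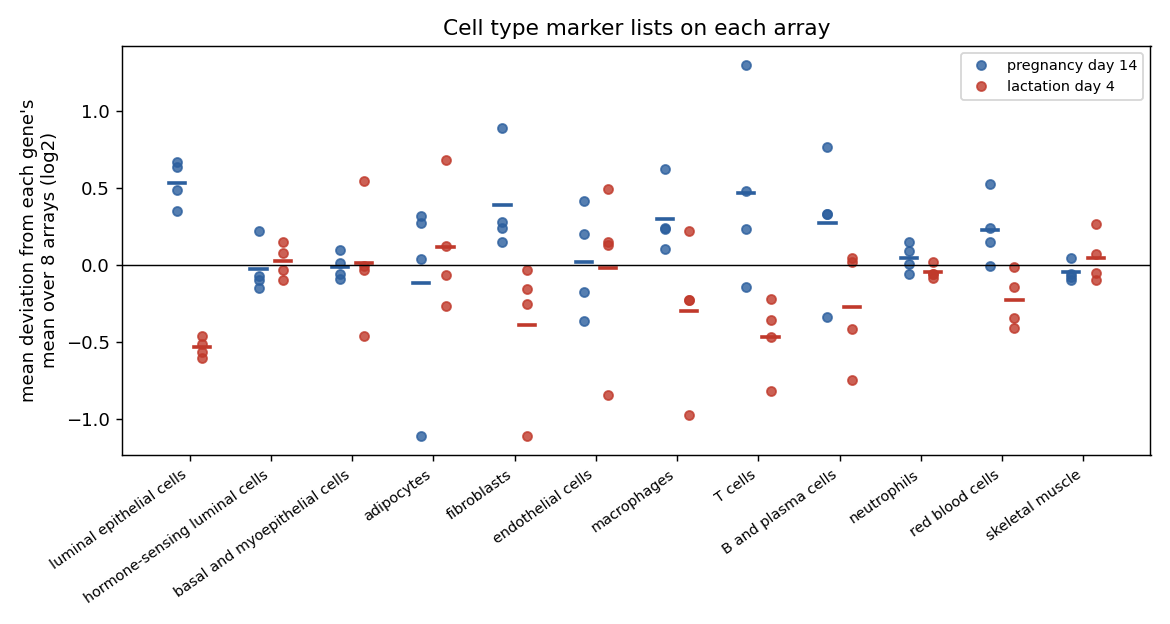
Mean deviation of each cell type marker list from its genes' means over 8 arrays (vertical axis, log2), for 12 lists (horizontal axis), with a point per array at pregnancy day 14 (blue) and lactation day 4 (red) and a bar for the stage mean. Luminal markers separate the stages, from 0.35 to 0.67 in pregnancy and from -0.60 to -0.46 in lactation. T cell markers also separate them, with a narrower gap, from -0.14 to 1.30 (replicate 2) in pregnancy and from -0.81 to -0.22 in lactation. So do fibroblast markers, from 0.151 to 0.889 in pregnancy and from -1.11 to -0.0308 in lactation. Red blood cell markers barely do, from -0.00567 to 0.524 in pregnancy and from -0.406 to -0.0156 in lactation.

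Some genes often used as references changed. Tfrc, the transferrin receptor, rose by 1.52, and Polr2a (-0.60), Hprt (-0.44) and Ywhaz (-0.43) fell, among 2 higher and 6 lower of 15 (2 and 7 adjusted over the list alone). The list's median was -0.19 and limma's camera gave an adjusted p of 0.333.

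**Figure D5:**
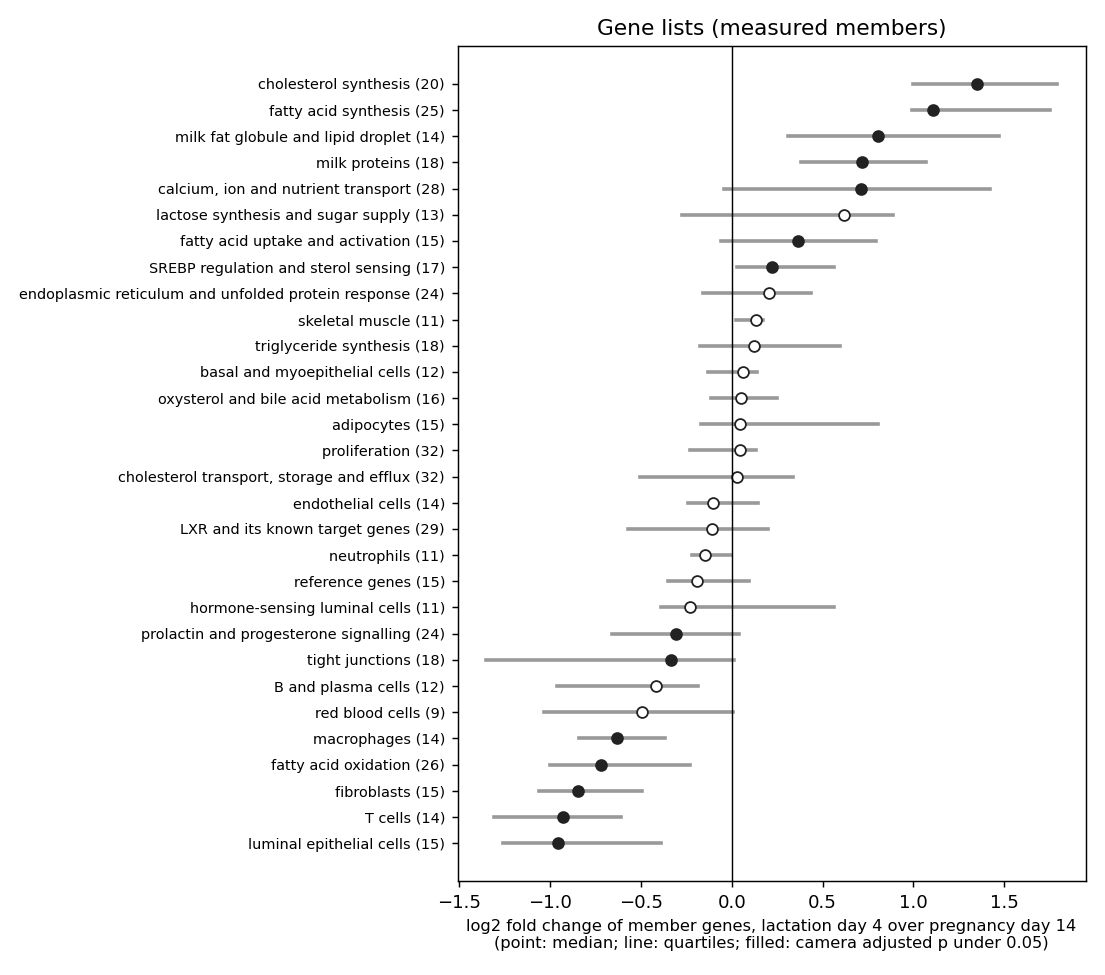
Median log2 fold change of lactation day 4 over pregnancy day 14 (horizontal axis) of the measured members of each of 30 gene lists (vertical axis, number of members in parentheses), with lines from the lower to the upper quartile over genes. Filled points are the 14 lists that camera called with a preset correlation, from cholesterol synthesis at 1.35 to luminal epithelial cells at -0.96.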

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

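Tests of the splits other than the total count, and the comparison restricted to T cell, fibroblast and macrophage markers, were chosen after the results were seen, as were the requirements that lists also move apart more than in other splits, and the restriction to lists that are neither dim nor of adipocytes. The macrophage term, the centring on brighter genes and the reading of its overshoot as undecided were likewise added then, as were the tests on LXR members chosen on other arrays and on the error of the macrophage mean. The number of called genes was not matched by any other division of the arrays: of the 35 splits of the 8 arrays into 4 and 4, only the stage split, 1 of 35, gave as many genes, 6463 against 0 in each of the other splits by limma, where the largest number at an unadjusted p under 0.05 was 2749 against 9813. The smallest share these splits can give is 2.86%. Since the labels do not tie arrays to separate mothers, the splits cannot exclude a chance difference between mothers or pools. The 2438 higher, 4025 lower, 397 at least 2-fold higher and 428 at least 2-fold lower genes, also 1 of 35 and 0 elsewhere, are parts of that count and no separate tests. For the camera calls, 1 of 35 splits gave as small a p for milk proteins (1.84e-12 against a smallest of 3.30e-10 in other splits), milk fat globule (7.69e-08 against 1.42e-06), fatty acid synthesis (6.78e-20 against 2.29e-12), fatty acid oxidation (8.36e-10 against 8.89e-07), cholesterol synthesis (1.43e-21 against 1.24e-10), nutrient transport (1.70e-07 against 8.81e-06), tight junctions (8.20e-05 against 1.15e-04) and luminal markers (1.26e-09 against 3.47e-07). By the rank of the camera p, chance was not excluded for fatty acid uptake (5 of 35 splits, 0.0183 against 3.15e-04), SREBP regulation (5 of 35, 0.00777 against 4.83e-04), prolactin and progesterone signalling (6 of 35, 0.0122 against 3.15e-04), T cells (13 of 35, 3.48e-05 against 2.98e-12), fibroblasts (18 of 35, 2.50e-04 against 4.47e-09) and macrophages (17 of 35, 0.00395 against 1.41e-11). That rank does not measure the size of the difference between the stages. In an exact test of list means over the splits, fatty acid uptake, SREBP regulation and prolactin and progesterone signalling each gave p = 0.0286, the smallest possible. Adjusted over all lists, each was 0.0536.

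T cell, fibroblast and macrophage markers were lower at lactation day 4, with a pooled median log2 fold change of -0.776 over 43 genes (95% bootstrap interval -0.965 to -0.600). An equal fall of the share of every other cell type is undecided. Of the 36 pairs of the 9 non-epithelial lists, 14 had intervals that did not overlap. The SD among the 9 shifts, 0.409, was as large in 1 of 35 splits (at most 0.379 in another). Both values go against an equal fall over all 9 lists. But 11 of the 14 pairs involve the neutrophil and skeletal muscle lists, with mean levels of 4.68 and 4.47 and little room to fall, or adipocytes, which the protocol removes. These lists also enter that SD. Among the other 6 lists 3 of 15 pairs did not overlap, endothelial markers against these 3 lists, and the SD among the 6 shifts, 0.307, was as large in 6 of 35 splits (at most 0.378 in another), so variation between arrays could part them as far. Milk transcripts taking up the signal would lower reference genes as far. Their interval, -0.370 to 0.138, lay above that of these 3 lists, but the gap between the medians, 0.587, was as large in 3 of 35 splits, that between the means, 0.729, in 1, and the lists were picked for their fall. Over all 115 non-epithelial markers, with a median of -0.240 (-0.402 to -0.165), the intervals overlap, so nothing is decided either way. Variation between arrays in how many such cells each digest held and a change of single cell types with the stage both stay open, the latter untested. For these 3 lists 13 to 18 of 35 splits gave as small a camera p, which does not measure the size of the fall. The difference between the stages in list mean was -0.931 for T cells, -0.778 for fibroblasts and -0.601 for macrophages. In an exact test over the splits these gave p = 0.0286, the smallest possible, 0.0286 and 0.0571. Adjusted over all lists they were 0.0536, 0.0536 and 0.0902. Every list at the smallest possible p had the same 0.0536, cholesterol synthesis and milk proteins among them, so no list passed 0.05. The adjusted values therefore decide nothing, and variation between arrays was not excluded.

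Of the LXR list, 12 members fell, with a median log2 fold change of -0.706, beside lower macrophage markers such as Lyz2 (9.98 to 8.67); the 2 lists share no gene, and the digestion is stated to deplete adipocytes. Fewer macrophages may contribute, since adding the macrophage marker mean to the limma fit brought the median of these members to -0.458 (95% bootstrap interval -0.714 to -0.324), and Pltp moved from -0.76 to -0.27. The interval lies below the -0.1 that macrophages as the whole cause would need. It was drawn over the 12 genes, which share the same 8 arrays, so it leaves out the error between arrays and decides nothing alone. These 12 were picked because they fell, which by itself pushes their median down. When members were instead picked at an unadjusted p under 0.05 on 2 arrays per stage and measured on the other 4 arrays, less the macrophage slope fitted over all 8, the median was -0.670 to -0.330 over the 36 choices. A marker mean with error would correct too little, but the 14 markers varied together within the stages (Cronbach's alpha 0.962), and dividing the slopes by this value gave a median of -0.452. At these slopes macrophages do not account for the whole fall, but the slopes may be too small. They come from differences within a stage, the largest in lactation day 4 replicate 2 (macrophage list mean -0.973, other lactation arrays -0.226 to 0.222). That array was also low in fibroblast (-1.11) and endothelial (-0.842) markers, and the choices of other arrays reuse the same slopes. Whether macrophages are the whole cause, a part or none thus stays open under the macrophage term. With that term 2 of the 12 passed the threshold, Abca1 at -1.17 (SE 0.209, adjusted p = 0.00853) and Mylip at -0.57 (SE 0.131, adjusted p = 0.0246; Pltp and Mylip are named for their values), as the stage term's variance was inflated 1.81-fold and calls over all genes went from 6463 to 2674. A change of these genes with the stage itself stays open, untested. The LXR list as a whole was not called (adjusted p = 0.338), and 4 members rose, among them Lpl (1.31) and Fasn (0.99).

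More genes were lower than higher, 62.3% of those called. If milk transcripts had moved the scaling, centring each array on its brighter 60% of genes was predicted to bring that share to 55% or less. It fell to 18.0%, but this decides nothing, since the centring itself sets the median of bright genes and overshot, raising dim genes along with them. Bright and dim genes moved apart, with medians of -0.11 over the brighter 60% of genes and 0.06 over the dimmer 40%, so that no single factor per array could remove both, and background correction, scaling and a real fall of many transcripts cannot be told apart.

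A sample far from the other 3 of its stage was found in 14 of 314 groups of 4 examined (4.46%, where chance flags about 1 in 20). In lactation day 4 replicate 2, Acadl was low at 5.39 against 6.24 to 6.36, Apoc1 low at 7.44 against 8.06 to 8.17, Pcp4 high at 8.94 against 7.95 to 8.11 and the fatty acid uptake list low at -0.0304 against 0.172 to 0.202. In lactation day 4 replicate 3 the proliferation list was low at -0.513, and in replicate 4 Cyp1b1 was high at 4.60. In pregnancy day 14 replicate 1, Agpat3 (8.82), Egf (5.07) and Nr1h2 (8.22) were high and Gpi1 (10.2) was low. In pregnancy day 14 replicate 2, Cldn4 (7.88) and Plin2 (11.6) were low, and in replicate 4 Muc1 (8.88) was high and Rspo1 (8.25) low. Among the 8720 probe sets without a gene name, which were left out of the comparisons of genes, 300 passed the threshold in limma, 141 higher and 159 lower, with log2 fold changes from -2.71 to 2.79.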

How the results depend on the processing

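Centring on the brighter 60% of genes and the macrophage term were added after seeing the data. Using the other deposited table in place of the main one was not run, since both hold the same values. The cause of the changes below was not tested, beyond fewer genes without the dim ones and fewer arrays when 1 is left out. Of the 122 called named genes, 103 kept call and direction under all of the up to 18 alternatives run for single genes, none changed direction, and 19 lost the call under at least 1: S100a8 (12 alternatives), Tph1 (11), Scp2 (10), Bub1b, Mfap5 and Nr1h2 (7 each), Abca7 and Plin2 (6), Col1a1, Col1a2, Hbb-bs and Mrc1 (5), Fabp5 (4), Lep and Mcat (3), Krt14 (2), and Hprt, Il7r and Stat5a (1). The macrophage term was fitted to all genes, with 2674 calls against 6463, but was read by gene for the LXR list only and is not in this tally. Values of lists are adjusted p of camera in limma, main values being those of the report. Without the dimmest 40% of genes: lactose 0.0196, triglycerides 0.014, endoplasmic reticulum 0.00875, prolactin and progesterone 0.341, macrophages 0.13, and turned direction for proliferation (0.391), hormone-sensing (0.272), endothelial (0.562) and neutrophil (0.526) lists. Quantile normalization: lactose 0.00888, triglycerides 0.0264, endoplasmic reticulum 0.0149, B cells 0.0249, red blood cells 0.0249, with proliferation (0.371), hormone-sensing (0.838), endothelial (0.812) and Abcg5 (-0.0649) turned. Centring on array medians: 3719 higher genes, fatty acid uptake 0.0903, B cells 0.0241 and basal turned (0.882). Centring on reference genes: fatty acid uptake 0.0544, B cells 0.0312, red blood cells 0.0499 and basal turned (0.938). Centring on the brighter genes: 10807 higher, 2373 lower and 257 at least 2-fold lower genes, fatty acid uptake 0.235, SREBP regulation 0.0761, B cells 0.00472, red blood cells 0.0208, with cholesterol transport (0.632), basal (0.637), adipocytes (0.803) and Cyp27a1 (0.0450) turned. Array weights: endoplasmic reticulum 0.0289, B cells 0.0212 and Abcg5 turned (-0.0135). The macrophage term left the LXR list uncalled (0.803) and ended the calls of Nr1h3 (-0.652, SE 0.123, to -0.555, SE 0.166, adjusted p = 0.066), Nr1h2 (-0.279, SE 0.0746, to -0.268, SE 0.105, 0.147), Abcg1 (-0.781, SE 0.157, to -0.507, SE 0.175, 0.103), Apoc1 (-1.18, SE 0.222, to -1.02, SE 0.303, 0.0633) and Plin2 (-0.288, SE 0.0763, to -0.353, SE 0.104, 0.0616). The SE rose for each of the genes just listed, and among them only for Abcg1 did the fold shrink by more than its SE. Further members, named afterwards for their values, also lost the call. They were Pltp (-0.759 to -0.267), Apoe (-0.570 to -0.296), Rxrb (-0.414 to -0.408), Tnfaip3 (-0.956 to -0.854) and Nrip1 (-0.308 to -0.375). Abca1 (-1.75 to -1.17) and Mylip (-0.816 to -0.574) kept it with a smaller fold. An estimated correlation gave milk proteins, milk fat globule, nutrient transport and luminal markers 0.0934 each, fatty acid oxidation 0.0652, fatty acid uptake and prolactin 0.229 each, SREBP regulation 0.322, tight junctions 0.186, fibroblasts 0.602, macrophages 0.622 and T cells 0.59. Fry gave lactose 0.0163, triglycerides 3.66e-04, reference genes 0.0219, fibroblasts 0.0818, macrophages 0.121, T cells 0.075 and the hormone-sensing list turned (0.924). Leaving out each array gave ranges of 1537 to 2487 higher, 2878 to 3939 lower, 367 to 430 at least 2-fold higher and 343 to 514 at least 2-fold lower genes. For lists it gave adipocytes 0.169 to 0.852, B cells 9.31e-04 to 0.167, basal 0.185 to 0.987, endoplasmic reticulum 0.00702 to 0.19, endothelial 0.129 to 0.929, fatty acid uptake 0.0155 to 0.0928, hormone-sensing 0.814 to 0.987, lactose 0.0129 to 0.101, proliferation 0.0381 to 0.997, red blood cells 0.0201 to 0.123, SREBP regulation 0.00483 to 0.0695, triglycerides 0.0425 to 0.124, and for Abcg5 log2 fold changes of -0.0179 to 0.0441. The lists of milk proteins, milk fat globule, nutrient transport, fatty acid synthesis and oxidation, cholesterol synthesis, tight junctions and luminal markers kept their camera call whichever array was left out and under each scaling. With each array left out, the call was also kept by T cells (5.66e-07 to 5.61e-04), fibroblasts (1.56e-04 to 0.00477), macrophages (5.92e-04 to 0.0398) and prolactin and progesterone (0.0186 to 0.0434). As small a camera p came from 6 to 18 of 35 splits for these.

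The labels do not say what a replicate number marks, and the letters in the titles are A, B, C and E in lactation and A, B, C and F in pregnancy, so number 4 joins different letters. Deviations of same-numbered arrays correlated at 0.24, 0.15 and 0.18 for numbers 1, 3 and 4 but at -0.16 for number 2, so the numbers were not taken to pair the arrays, although 5 of 8 arrays, not all, correlated best with their own number, a hint of shared variation from the data and not the design. With the number as a block, 2530 genes were higher and 3935 lower, 399 and 423 of them at least 2-fold, fatty acid uptake gave 0.0669, B cells 0.00714 and the basal list turned (0.999), with no other list call changed. Signal over background limits dim genes, which cannot fall below the lower end of the GC-RMA values, 2.04.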

Other observations

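The gene families in this part were chosen by symbol after seeing the data, and so was the test of the splits. Zinc transporters changed in both directions at lactation day 4, 9 higher and 2 lower of 24. Beside Slc39a4 (-3.59), Slc39a8 (2.92) and Slc30a2, which loads zinc into vesicles (2.58), Slc39a6 (1.56), Slc39a11 (0.87) and Slc39a10 (0.85) rose. Of 23 subunits and partners of the vacuolar proton pump, 3 rose and 4 fell, with Atp6v1b1 (-3.05) and Atp6v1c2 (-1.998) falling and Atp6v0a1 (0.83) rising. Among 31 integrins Itga2 (-1.98), Itgb8 (-1.64) and Itgb4 (-0.88) fell and Itga8 (1.14) and Itgav (1.12) rose. Wfdc3 (2.25) and Wfdc17 (2.20), of the whey acidic protein family, rose among 4 of 18. Chemokines went both ways, with Ccl28 (4.59) and Cxcl14 (1.01) higher and Cxcl16 (-1.45), Ccl8 (-0.81) and Cxcl12 (-0.71) lower. All of these passed the threshold over all genes in limma.

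Cytosolic ribosomal proteins and their paralogs had a median of -0.24, with 57 of 86 genes lower and 2 higher, among them Rpl22 (-0.75) and Rps27l (0.95). Proteasome subunits fell in 15 of 39 cases, with Psmd10 (-1.01) and the immunoproteasome subunits Psmb9 (-0.95), Psmb8 (-0.92) and Psmb10 (-0.85), beside lower T cell and macrophage markers (list medians of -0.927 and -0.629), and 9 of 36 complex I subunits rose, led by Ndufa1 (0.64). The direction of these 3 medians was the same under each of 4 other scalings, but their size was not. With arrays centred on the brighter genes the medians were -0.067 for ribosomal proteins, -0.0583 for the proteasome and 0.35 for complex I, against -0.242, -0.233 and 0.175. Camera in limma gave adjusted p-values of 5.01e-12, 2.85e-04 and 0.00135, with adjusted p = 0.405, 0.672 and 0.672 with an estimated correlation. Calls of 7 families in all were matched in 5 of 35 splits of the arrays, the highest other split calling 8, so chance is not excluded for their number.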
